A study of Mus musculus with 4 samples.

How the data were processed

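RNA was measured in 4 libraries of splenic helper T cells, 2 labelled wild type and 2 labelled as lacking RIPK1 in T cells. Per the labels' protocols, RNA was extracted with Direct-zol kits, and libraries were made from 200 ng of total RNA with the NEBNext Ultra RNA kit. The series design names an Illumina HiSeq 1500. Bowtie 0.12.2 and the genome build mm8 are named, per the submitters' processing notes; the program that computed the values, its annotation and its filters are not given in the sources used here. The authors deposited 1 table per library with an FPKM value per gene symbol, per the file headers, and no library was pooled. FPKM divides the fragments of a gene by its length and by the mapped total of its library, so a few abundant genes that change can shift all others, and lengths enter every value.

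Each table held 23700 rows with 23234 different symbols. Of these symbols 250 stood on more than 1 row (716 rows), and each row was tested on its own; 25 symbols had been turned into dates and were left as they stood. Positions are not given, because the tables hold none and the annotation used here is of another build than mm8. Transcript lengths were those of the longest transcript of each symbol in that annotation and were found for 22752 symbols. They served to check for length bias, to estimate depth and to point out short RNA genes. Of 575 list symbols, 11 were matched through a synonym and 10 were not matched. Where whole fragments are counted, the ratio of a low value (0.005 to 0.15 FPKM) between libraries is a ratio of small whole numbers times the relative depth. Between 42.4% and 54.7% of low genes lay on such ratios within 0.01 on the log2 scale, against 4.0% to 5.7% off the steps, and the fragments were 0.825 and 0.898 times as many in KO 1 and KO 2 as in WT 1. Absolute depth was estimated from genes with 1 transcript with an assumed fragment length of 200 nt (17100000 to 21400000 fragments); 71.3% to 76.1% of the values were within 5% of a whole number of fragments. Because fragments were not recovered for nearly all genes, no test for counts was run.

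The main test was limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(FPKM + 1), for genes with at least 1 FPKM in at least 2 of the 4 libraries. Tests were two-sided, and adjusted p-values are those of Benjamini and Hochberg over the genes tested, with a threshold of 0.05. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and folds are ratios of mean FPKM. Gene lists were tested with camera (limma) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 33 lists with at least 3 tested members, with an estimated correlation, and with fry (limma). With an estimated correlation 0 lists passed (smallest adjusted p = 0.681) and 0 had an unadjusted p under 0.05; fry called 1 list higher and 0 lower, with 15 and 0 at an unadjusted p under 0.05. fry's test asks whether the genes of a list move on balance in 1 direction and does not set them against other genes. Trimmed-mean scaling was an own implementation of the trimmed mean of M values (30% of log ratios and 5% of mean levels trimmed at each side); the library factors were 0.791, 0.905, 1.21 and 1.16 in WT 1, WT 2, KO 1 and KO 2. Scripts ran in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9).

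The design, the gene lists, the rule for named genes and most alternative settings were fixed before the data were examined. The rule named Ripk1, Ripk3, Mlkl and Casp8, the 12 largest rises and the 12 largest falls among called genes with given names whose groups did not overlap, up to 4 members of each described list by unadjusted p, and up to 3 members of each list of markers of another cell type by mean value. Since most of the 12 rises were small RNA genes, the same rule was applied again with small RNA and ribosomal protein genes left out, after the values were seen. A few genes are not reported here. The alternatives were each library left out in turn, a block for the replicate number, pseudocounts of 0.1 and 5, other filters, quantile and trimmed-mean scaling, other forms of the limma test, another threshold and a minimum fold of 2. Added after seeing the data were tests without small RNA genes, without rows at 0 in any library, and with the trend on transcript length removed from each library.

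The procedure was tested on simulated data for this comparison, with 11074 genes and 10 runs of 100 genes changed at each size. It recovered 54.2% of genes changed 2-fold and 99.1% of those changed 4-fold. Recovery was not split by the level of the changed genes. These percentages are therefore not shown to hold for genes with low FPKM, such as Mki67, Itgae, Ccr6 and Csf1 in the wild type. Of the calls 8.58% were false, a larger share than the adjusted p threshold of 0.05 aims at. A list of 20 genes raised 2-fold was called in 10 of 10 runs, and 0 of 200 unchanged lists were called. The runs changed far fewer genes than the 2832 called higher as deposited, where the median gene rose by 0.38 (log2). They therefore do not show how often lists are falsely called under such a shift, or when genes of a list move together.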

Results

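Helper T cells were taken from the spleens of C57BL/6 mice 43 weeks old, and their RNA was sequenced. The libraries of 1 group are labelled wild type (WT 1 and WT 2), and those of the other KO (KO 1 and KO 2), for a deletion of RIPK1 in T cells only. RIPK1 is a kinase and scaffold of the TNF receptor complex that takes part in NF-kB signalling, apoptosis and necroptosis. Each library gave 1 FPKM value (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for each of 23700 rows named by gene symbol. The depth read from the steps of the low values was about 20900000 and 21400000 fragments in WT 1 and WT 2, and 17100000 and 18600000 in KO 1 and KO 2. A transcript of 2 kb at 1 FPKM then rested on 30.7 to 38.5 fragments. Across genes, log2 values of WT 1 and WT 2 had a Pearson r of 0.951 and those of KO 1 and KO 2 of 0.952, against 0.897 to 0.932 for pairs from different groups; genes are not independent replicates. The labels do not say that the 2 libraries of a group came from separate mice, so p-values measure the spread between these libraries, which may be technical.

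The single comparison was between the genotypes. The targeted gene was not lower in the libraries labelled KO. Ripk1 stood at 5.61 and 5.60 FPKM in WT 1 and WT 2 and at 10.4 and 9.54 FPKM in KO 1 and KO 2, a log2 change of 0.73 ± 0.17 (SE, limma adjusted p = 0.0262), or 0.35 above the median gene. The value therefore goes against the label, and every direction below is that of the libraries labelled KO. The part of Ripk1 deleted is not given in the sources used here, and a value for the whole gene does not check a deletion of some exons. Ripk3, the kinase that RIPK1 activates in necroptosis, rose from 5.38 ± 1.69 to 15.5 ± 1.24 FPKM (SD, n = 2 and 2; limma adjusted p = 0.0142). Casp8, the protease that cleaves RIPK1 and RIPK3, was at 24.3 ± 1.67 and 31.6 ± 2.66 FPKM (SD, n = 2 and 2), a difference that did not pass (limma adjusted p = 0.198). Mlkl, the pore-forming effector of necroptosis, was too low to be tested, at 0.342 and 0.0301 FPKM in the wild type and 1.21 and 0.312 FPKM in the libraries labelled KO. After trimmed-mean scaling the log2 change of Ripk1 was 0.31 and no longer passed (limma adjusted p = 0.222), and that of Casp8 was -0.10. Leaving out WT 1, WT 2 or KO 1 also ended the call for Ripk1, at adjusted p = 0.0991, 0.0552 and 0.109 in limma.

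**Figure D1:**
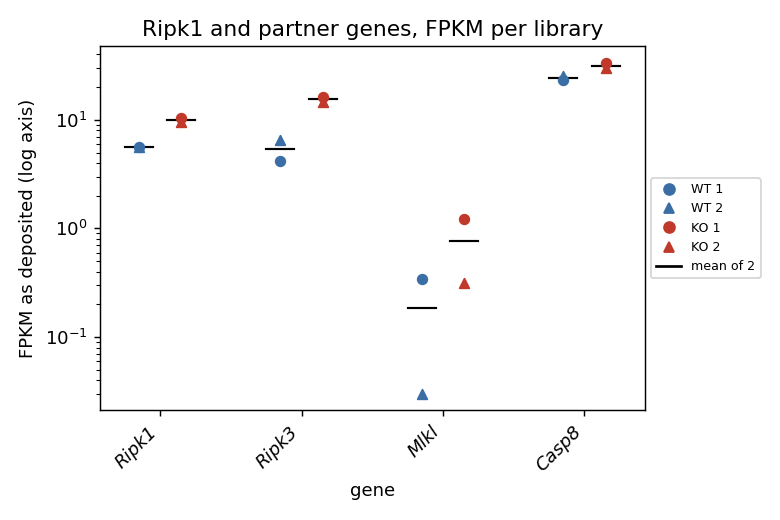
FPKM as deposited (log axis) of Ripk1, Ripk3, Mlkl and Casp8 in each of the 4 libraries, with bars at the mean of 2. Both libraries labelled KO sit above both wild-type libraries for Ripk1 (10.4 and 9.54 against 5.61 and 5.60 FPKM) and Ripk3.

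Of 33 gene lists, 13 were higher in the libraries labelled KO by camera (limma). Among them were those of follicular helper, regulatory, Th1 and Th17 cells, of the cell cycle, and of erythroid markers, which stand for another cell type. Some lists share members, so the 13 are not independent. Il21 is in the follicular helper, Th17 and common gamma chain lists. Tnf is in the Th1, senescence secretory and NF-kB lists, and Tox and Tox2 are in the follicular helper and exhaustion lists. Genes for ribosomal proteins were lower, and those of the respiratory chain lay below the median gene. These group changes passed camera only with its preset correlation (smallest adjusted p = 0.681 with an estimated correlation, limma). The preset value is an assumption, and 2 libraries per group estimate a correlation poorly, so neither form settles a list. The adjusted p of 0.681 repeated below is shared by lists with different unadjusted p in that camera test (limma). Examples are Th17 genes (0.0621), ribosomal protein genes (0.118) and naive genes (0.453). Of 11074 genes tested as deposited, 2832 were higher and 111 lower at an adjusted p of 0.05 (limma), so that 96.2% of the calls were higher. The genes called higher were 25.6% of all tested genes, and the rises counted for each list as deposited are to be read against that share. After trimmed-mean scaling 518 were higher and 576 lower (47.3% higher), and after quantile normalization 179 and 77 (69.9% higher). Counts given after these scalings are to be read against these totals and not against the 25.6%. The 518 and 106 of the 111 passed both as deposited and after trimmed-mean scaling. The median gene changed by 0.38 on the log2 scale as deposited and by -0.01 after trimmed-mean scaling, so changes of gene groups are given relative to the median gene. Without WT 1, 9 genes were higher and 0 lower in limma, with 3069 and 340 at an unadjusted p under 0.05; without KO 1 the counts were 1611 and 70. No permutation of 2 against 2 libraries can give a two-sided p under 0.333.

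The 12 largest rises, apart from small RNA and ribosomal protein genes, were 4 globin rows (Hba-a2 on 2 rows, Hbb-b2 and Beta-s), which are markers of erythroid cells, and Penk (proenkephalin), Spp1 (osteopontin), Rgs16, Mki67, Il21, Tox2, Bhlhe40 and Top2a; this selection was made after the values were seen. The globin rows passed as deposited (limma adjusted p = 0.0353 to 0.0432) and not after trimmed-mean scaling (adjusted p = 0.0757 to 0.0909), and Rgs16 likewise (0.0449 and 0.101, limma). Their log2 changes stayed large, at 3.63 as deposited and 3.21 after trimmed-mean scaling for Hba-a2, and 3.05 and 2.68 for Rgs16. Spp1 rose from 1.57 ± 1.19 to 21.9 ± 5.50 FPKM (SD, n = 2 and 2; limma adjusted p = 0.0106), and Penk from 2.01 ± 1.37 to 28.9 ± 11.2 FPKM (limma adjusted p = 0.0106). Bhlhe40, a transcription factor of cytokine-producing T cells, rose from 10.3 ± 10.4 to 64.7 ± 25.6 FPKM (limma adjusted p = 0.0263), a call that trimmed-mean scaling ended (adjusted p = 0.0635, limma). Its log2 change was 2.89 as deposited and 2.45 after that scaling. The largest falls included Dapl1, found in naive T cells, from 53.8 ± 4.98 to 13.9 ± 7.10 FPKM (limma adjusted p = 0.0151). Ly6c1, a surface protein of memory T cells, fell from 36.6 ± 3.29 to 10.4 ± 1.68 FPKM (limma adjusted p = 0.0112), and Cd55, a regulator of complement, from 11.5 ± 0.0668 to 3.69 ± 0.666 FPKM (limma adjusted p = 0.0127). Adh1, an alcohol dehydrogenase, fell from 5.84 ± 2.51 to 1.69 ± 0.307 FPKM (limma adjusted p = 0.0212).

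**Figure D2:**
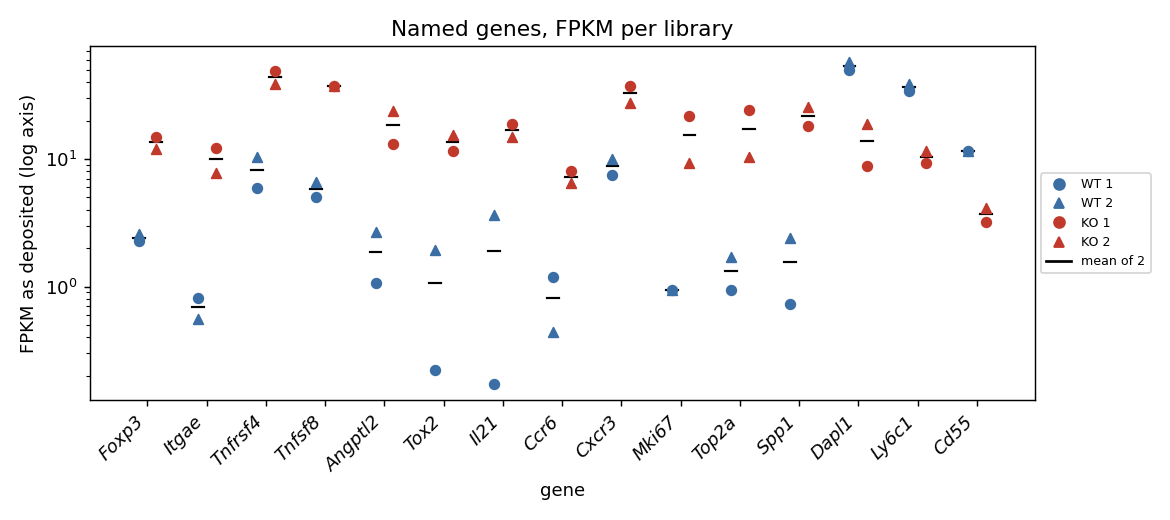
FPKM as deposited (log axis) of 15 genes in each of the 4 libraries, with bars at the mean of 2. The wild-type libraries lie below the libraries labelled KO for Foxp3, Itgae, Tnfsf8 and the other risen genes, and above them for Dapl1, Ly6c1 and Cd55.

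Genes of follicular helper T cells, which help B cells in germinal centres, were higher as a group. Of 19 tested, 18 rose as deposited, all 19 adjusted over the list alone, 11 after trimmed-mean scaling and 6 after quantile normalization, and the median was 1.60 above the median gene (log2). Tnfsf8 rose from 5.81 ± 1.07 to 37.5 ± 0.114 FPKM (SD, n = 2 and 2; limma adjusted p = 0.00558). Pou2af1, a transcriptional coactivator, rose 5.48-fold (limma adjusted p = 0.00707), Tox 3.38-fold and Angptl2 9.85-fold (both limma adjusted p = 0.0127). Il21, the helper cytokine, was at 0.172 and 3.62 FPKM in WT 1 and WT 2 and averaged 17.0 ± 2.82 FPKM in the libraries labelled KO (limma adjusted p = 0.0179). Among 33 lists the group passed camera with its preset correlation (limma, adjusted p = 9.93e-07), with adjusted p = 0.681 with an estimated correlation.

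Genes of regulatory T cells were higher too. Of 20 tested, 17 rose as deposited, 18 adjusted over the list alone, 10 after trimmed-mean scaling and 8 after quantile normalization, with a median 1.05 above the median gene. Foxp3, the lineage transcription factor, rose from 2.41 ± 0.215 to 13.5 ± 2.09 FPKM, and Itgae, the integrin CD103, 14.6-fold from 0.686 ± 0.179 FPKM (SD, n = 2 and 2; both limma adjusted p = 0.0078). Tnfrsf4, the receptor OX40, rose 5.34-fold (limma adjusted p = 0.0115), and Nt5e, the ectonucleotidase CD73, 4.70-fold (limma adjusted p = 0.0123). The group passed camera (limma, adjusted p = 2.94e-05), with adjusted p = 0.681 with an estimated correlation.

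All 7 tested Th17 genes rose, both as deposited and after trimmed-mean scaling, and 7 adjusted over the list alone; after quantile normalization 2 did. Ccr6, the chemokine receptor of Th17 cells, rose from 0.816 ± 0.528 to 7.23 ± 1.07 FPKM (SD, n = 2 and 2; limma adjusted p = 0.0106), and Rora, a nuclear receptor gene, rose 6.72-fold (limma adjusted p = 0.0115). The group passed camera (limma, adjusted p = 0.00113; adjusted p = 0.681 with an estimated correlation), and it was the 1 list past fry (limma, adjusted p = 0.00853; 2 lists after trimmed-mean scaling), which tests whether the genes of a list move on balance in 1 direction. Of 14 Th1 genes 9 rose, 12 adjusted over the list alone, 4 after trimmed-mean scaling and 3 after quantile normalization (camera adjusted p = 0.00532, limma; adjusted p = 0.681 with an estimated correlation). Cxcr3, the chemokine receptor of Th1 cells, rose from 8.75 ± 1.79 to 32.7 ± 7.13 FPKM (limma adjusted p = 0.0127) and Tnf 2.94-fold (limma adjusted p = 0.0131). Of 7 Th2 genes 3 rose, 4 adjusted over the list alone, 1 after trimmed-mean scaling and 1 after quantile normalization, and the list did not pass camera as deposited (limma, adjusted p = 0.0952; adjusted p = 0.681 with an estimated correlation). It did pass after trimmed-mean scaling (adjusted p = 0.0162, limma), after quantile normalization (0.0181), with the replicate number as a block (0.00187) and without KO 1 or KO 2 (0.000135 and 0.000173), so the group is left open. Its risen members were Ccr8 (11.5-fold, limma adjusted p = 0.0127), Il4 (from 1.23 ± 0.900 to 8.61 ± 5.44 FPKM, limma adjusted p = 0.0216) and Gata3 (2.09-fold, limma adjusted p = 0.044).

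Effector and memory genes were higher, and naive genes lay below the median gene. Of 25 effector and memory genes, 16 rose and 1, Ly6c1, fell; adjusted over the list alone 18 rose and 1 fell, and after trimmed-mean scaling 13 rose and 1 fell and after quantile normalization 8 and 1 (camera adjusted p = 0.00335, limma; adjusted p = 0.681 with an estimated correlation). Ahnak rose 5.97-fold and Anxa2 7.18-fold (both limma adjusted p = 0.0106). Of 24 naive and quiescent genes, 3 rose (Ets1, Tcf7 and Il7r) and 2 fell (Dapl1 and 2610019F03Rik), against 0 and 1 adjusted over the list alone, 0 and 3 after trimmed-mean scaling and 0 and 2 after quantile normalization. The naive list was lower by camera (limma, adjusted p = 0.00898; adjusted p = 0.681 with an estimated correlation), a call lost without WT 2 (adjusted p = 0.113), without KO 1 (0.214) and with no filter (0.202). Its relative median ran from -0.56 to -0.18 on leaving out 1 library and was -0.03 with no filter. Its median and mean were 0.07 and 0.00 above no change as deposited and -0.31 and -0.38 relative to the median gene, so its direction as deposited differs from that of the test. Tcf7, a transcription factor of naive and memory T cells, rose from 143 ± 23.3 to 259 ± 17.0 FPKM (SD, n = 2 and 2; limma adjusted p = 0.0418), a call lost after trimmed-mean scaling (adjusted p = 0.153, limma). Of 13 inhibitory receptor and exhaustion genes 10 rose, 10 adjusted over the list alone, 7 after trimmed-mean scaling and 6 after quantile normalization (camera adjusted p = 0.00446, limma; adjusted p = 0.681 with an estimated correlation); Nfatc1 rose 3.40-fold and Tox2 12.6-fold (limma adjusted p = 0.0127 and 0.0129). Of 16 cytotoxicity genes 6 rose as deposited, 9 rose and 1 fell adjusted over the list alone, 3 rose and 1 fell after trimmed-mean scaling and 0 rose after quantile normalization, and the list did not pass (camera adjusted p = 0.509, limma), except with the stricter filter, which left 6 genes (adjusted p = 0.0373). Gzmk, a granzyme, rose 3.47-fold (limma adjusted p = 0.0131) and Eomes 3.22-fold (limma adjusted p = 0.0127).

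**Figure D3:**
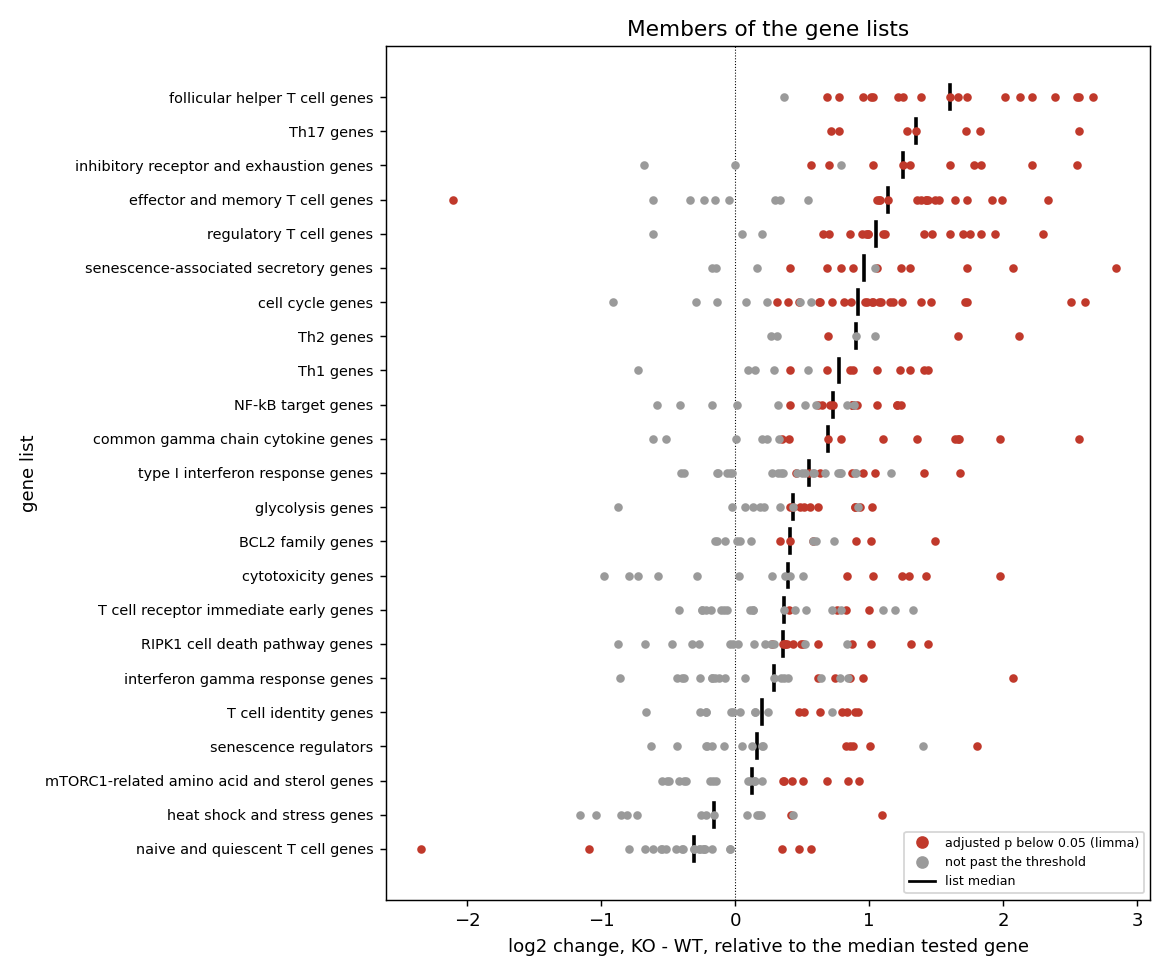
Log2 change relative to the median tested gene (x axis) of each tested member of 23 gene lists (y axis), red where the adjusted p is below 0.05 in limma, with a bar at the list median. Follicular helper T cell genes have the highest median (1.60) and naive and quiescent genes the lowest (-0.31).

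Cell cycle genes were higher. Of 30 tested, 23 rose as deposited, 25 adjusted over the list alone, after trimmed-mean scaling 10 rose and 1 fell, and after quantile normalization 2 rose. Mki67, the proliferation antigen, was at 0.939 and 0.937 FPKM in the wild type and at 21.7 and 9.39 FPKM in KO 1 and KO 2 (limma adjusted p = 0.0111). Top2a, which untangles DNA at mitosis, rose 13.1-fold (limma adjusted p = 0.0127), and Bub1b, of the spindle checkpoint, 9.17-fold (limma adjusted p = 0.014). The group passed camera (limma, adjusted p = 8.68e-05; adjusted p = 0.681 with an estimated correlation). Erythroid markers moved the same way: 7 of 8 rose, 7 adjusted over the list alone, 3 after trimmed-mean scaling and 2 after quantile normalization (camera adjusted p = 0.0379, limma; adjusted p = 0.681 with an estimated correlation, and 0.0544 and 0.13 with pseudocounts of 0.1 and 5). The globin gene Hba-a2 was at 2.07 and 32.3 FPKM in WT 1 and WT 2 and at 140 and 111 FPKM in KO 1 and KO 2. Of 40 rows for replication-dependent histone genes, 10 rose as deposited and adjusted over the list alone, while after trimmed-mean scaling 0 rose and 1 fell and after quantile normalization 0 passed. As deposited, that share lay near the 25.6% of all tested genes. The histone list was lower by camera (limma, adjusted p = 0.027; adjusted p = 0.681 with an estimated correlation), with a median of -0.35 and a mean of -0.17 relative to the median gene but 0.03 and 0.21 as deposited. That call was lost after trimmed-mean scaling (adjusted p = 0.635, limma) and quantile normalization (0.358) and without WT 2, KO 1 or KO 2 (0.2, 0.278 and 0.437), and the median changed sign with either other filter and with the length trend removed. Many histone copies are near-identical, so their values are uncertain.

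Genes for secreted factors of senescent cells were higher, while the regulators of senescence did not pass as a group as deposited. Of 14 tested genes of the secretory list, 10 rose, 10 adjusted over the list alone, 4 after trimmed-mean scaling and 3 after quantile normalization (camera adjusted p = 0.00532, limma; adjusted p = 0.681 with an estimated correlation and 0.405 with no filter). Besides Spp1 and Tnf they included Csf1, a macrophage growth factor, from 0.444 ± 0.116 to 5.24 ± 0.886 FPKM (SD, n = 2 and 2; limma adjusted p = 0.0078), and the adhesion molecule Icam1 (3.50-fold, limma adjusted p = 0.0143). Of 16 senescence regulators 5 rose, 6 adjusted over the list alone, 2 after trimmed-mean scaling and 0 after quantile normalization (camera adjusted p = 0.387, limma). They passed without WT 2 (adjusted p = 0.0476, limma) and without KO 1 (0.00107), and their relative median ran from 0.02 to 0.40 on leaving out 1 library. Rb1, the retinoblastoma gene, rose 2.67-fold (limma adjusted p = 0.0129), and Cdkn2c, an inhibitor of cyclin-dependent kinases, 2.73-fold (limma adjusted p = 0.0156). Glycolysis genes were higher, 10 of 19 as deposited, 16 adjusted over the list alone, 3 after trimmed-mean scaling and 4 after quantile normalization (camera adjusted p = 0.00748, limma; adjusted p = 0.681 with an estimated correlation), with Hk1 2.78-fold higher (limma adjusted p = 0.0131). Of 22 amino acid and sterol genes tied to mTORC1, 7 rose, 7 adjusted over the list alone, 1 after trimmed-mean scaling and 0 after quantile normalization (camera adjusted p = 0.52, limma, and 0.0432 with no filter). Slc1a5, a glutamine transporter, rose 2.38-fold (limma adjusted p = 0.0173). As deposited, the shares of senescence regulators and of mTORC1-related genes called higher lay not far above the 25.6% of all tested genes.

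NF-kB targets and genes of the common gamma chain cytokines were higher. Of 23 NF-kB targets 14 rose, 15 adjusted over the list alone, 6 after trimmed-mean scaling and 4 after quantile normalization (camera adjusted p = 0.00689, limma; adjusted p = 0.681 with an estimated correlation). Nfkb2, a subunit of NF-kB, rose from 6.65 ± 0.827 to 21.9 ± 2.14 FPKM (SD, n = 2 and 2; limma adjusted p = 0.0115). Of 17 common gamma chain genes 11 rose, 14 adjusted over the list alone, 5 after trimmed-mean scaling and 3 after quantile normalization (camera adjusted p = 0.0058, limma; adjusted p = 0.681 with an estimated correlation). Il2rb, a subunit of the receptors for IL-2 and IL-15, rose 4.23-fold and Cish, an inhibitor of cytokine signalling, 6.73-fold (both limma adjusted p = 0.0127). Of 27 genes of the RIPK1 cell death pathway 13 rose, 17 adjusted over the list alone, and 4 rose and 1 fell after trimmed-mean scaling and 2 and 1 after quantile normalization (camera adjusted p = 0.0494 as deposited, 0.0566 after trimmed-mean scaling, 0.14 without WT 2 and 0.122 with the length trend removed, limma; adjusted p = 0.681 with an estimated correlation). Tnfrsf1b, the TNF receptor TNFR2, rose 3.65-fold (limma adjusted p = 0.0136).

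The remaining state lists did not pass camera as deposited, and some passed under other settings. After quantile normalization 0 genes rose in the first 4 lists below. As deposited, the shares of type I interferon and interferon gamma genes called higher lay near the 25.6% of all tested genes. Of 15 BCL2 family genes 6 rose, 8 adjusted over the list alone and 2 after trimmed-mean scaling (camera adjusted p = 0.0753 as deposited, 0.0418 after trimmed-mean scaling and 0.0307 after quantile normalization, limma), among them Bak1 (2.95-fold, limma adjusted p = 0.0139). Of 31 type I interferon response genes 8 rose, 9 adjusted over the list alone and 0 after trimmed-mean scaling (camera adjusted p = 0.0699 as deposited, 0.00646 after trimmed-mean scaling, 0.00419 after quantile normalization and 0.875 without KO 1, limma), among them Oas1a (4.78-fold, limma adjusted p = 0.0197). Of 23 interferon gamma response genes 5 rose, 5 adjusted over the list alone and 1 after trimmed-mean scaling (camera adjusted p = 0.547 as deposited and 0.317 after trimmed-mean scaling, limma), among them Nlrc5 (2.47-fold, limma adjusted p = 0.0143). Of 23 immediate early genes of T cell receptor signalling 4 rose, 2 adjusted over the list alone and 0 after trimmed-mean scaling (camera adjusted p = 0.509 as deposited, 0.148 after trimmed-mean scaling and 0.0147 after quantile normalization, limma), among them Ier3 (3.14-fold, limma adjusted p = 0.0151). Of 15 heat shock and stress genes 2 rose as deposited, Hmox1 and Txnrd1, and 2 adjusted over the list alone, while 0 rose and 4 fell after trimmed-mean scaling and 0 and 1 after quantile normalization (camera adjusted p = 0.109, limma). The heat shock list was lower by camera and relative to the median gene, with a median of 0.22 and a mean of 0.20 above no change as deposited. Of 18 T cell identity genes 7 rose, 7 adjusted over the list alone, and after trimmed-mean scaling 3 rose and 1 fell, after quantile normalization 4 rose (camera adjusted p = 0.0753 as deposited, 0.223 after trimmed-mean scaling and 0.000526 after quantile normalization, limma). Cd4 itself rose from 86.8 ± 0.738 to 198 ± 17.9 FPKM (SD, n = 2 and 2; limma adjusted p = 0.0173).

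Ribosomal protein genes were lower as a group. Of 79 tested, 31 fell as deposited, 54 adjusted over the list alone, 73 after trimmed-mean scaling and 5 after quantile normalization, and 0 rose under any of the 3. Their median was -1.26 relative to the median gene as deposited and -0.16 after quantile normalization. Rps21 fell from 2922 ± 591 to 1136 ± 11.5 FPKM (SD, n = 2 and 2; limma adjusted p = 0.0212), and Rps24 from 3030 ± 361 to 1225 ± 37.2 FPKM (limma adjusted p = 0.0206). Together they made up 36.6% and 38.8% of the FPKM sum in WT 1 and WT 2 and 22.3% and 22.6% in KO 1 and KO 2. The list was lower by camera (limma, adjusted p = 6.2e-57; adjusted p = 0.681 with an estimated correlation). Nuclear genes of the mitochondrial respiratory chain lay below the median gene (median -0.43 and mean -0.44 relative to it) but close to no change as deposited (-0.05 and -0.06). Of 74 tested, 2 fell as deposited, 0 adjusted over the list alone, 17 after trimmed-mean scaling and 2 after quantile normalization (camera adjusted p = 6.56e-08, limma; adjusted p = 0.681 with an estimated correlation and 0.112 with the length trend removed; fry adjusted p = 0.853). At an unadjusted p under 0.05, 3 were higher and 5 lower as deposited. Ndufa2, of complex I, fell from 138 ± 2.12 to 70.6 ± 12.8 FPKM (limma adjusted p = 0.0282), and Atp5e, of ATP synthase, from 332 ± 23.7 to 174 ± 11.9 FPKM (limma adjusted p = 0.0305). Many ribosomal protein genes have processed pseudogenes that can share their reads, so single members are uncertain.

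Small RNA genes gave the largest fitted changes. Of 106 tested, 13 were called higher and 6 lower (limma), and the libraries differed in which of these genes were listed at 0. Snord72, a small nucleolar RNA, was listed at 0 in both wild-type libraries and at 428 and 185 FPKM in KO 1 and KO 2, and Mir142 was listed at 0 in both and at 156 and 545 FPKM. Snord11, Mir2861, Mir135a-1, Snord87, Mir1938, Mir7-1 and Mir697 were likewise listed at 0 in WT 1 and WT 2, and Snora24 and Mir546 were below 10 FPKM there. Scarna2 was listed at 809 and 157 FPKM in the wild type and at 0 in both libraries labelled KO. Snord47, Mir1902, Mir1965 and Snora17 were also called lower. Of 131 rows at 0 in 1 library and above 10 FPKM in another, 114 were small RNA genes with symbols that start with Mir, Snor or Scarna. Among the others, which include further small RNA genes, Irak1 was at 37.0, 34.2 and 35.8 FPKM in WT 1, KO 1 and KO 2 and listed at 0 in WT 2. A value of 0 therefore does not show that a gene was silent. High values of short genes are uncertain as well. Snord72 and Mir142 are 81 and 64 nt long in the annotation used here, shorter than the fragment length of 200 nt assumed for the depth, while Scarna2 is 414 nt long.

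Of the marker lists of other cell types, only the erythroid list passed camera as deposited. B cell markers did not pass as a list (camera adjusted p = 0.989, limma), with 3 of 6 higher, 3 adjusted over the list alone, 1 after trimmed-mean scaling and 0 after quantile normalization, a median 0.11 and a mean 0.05 above the median gene and a downward camera direction. Cd79a, part of the B cell receptor, stood at 3.19, 3.13, 2.93 and 4.90 FPKM in WT 1, WT 2, KO 1 and KO 2, while Cd22 rose 2.64-fold (limma adjusted p = 0.0144). Fcer2a, the member with the highest values, was at 17.0 ± 3.11 and 12.4 ± 0.0139 FPKM (SD, n = 2 and 2; limma adjusted p = 0.166). Of 7 tested dendritic cell markers 4 rose, 4 adjusted over the list alone (camera adjusted p = 0.565, limma), and after trimmed-mean scaling 2 rose and 1 fell and after quantile normalization 1 rose; without KO 2 the list passed (adjusted p = 0.000905, limma). Cd74, the MHC class II invariant chain, rose from 8.71 ± 2.55 to 46.6 ± 17.7 FPKM (limma adjusted p = 0.0129). Xcr1 was at 18.0 ± 2.24 and 13.4 ± 0.456 FPKM (limma adjusted p = 0.165, and 0.0497 as a fall after trimmed-mean scaling), and Siglech at 10.9 to 13.8 FPKM in the 4 libraries (limma adjusted p = 0.592). Of 6 macrophage and monocyte markers 3 rose, 3 adjusted over the list alone, while 1 rose and 1, Ms4a6c, fell after trimmed-mean scaling and 0 passed after quantile normalization (camera adjusted p = 0.584, limma). Among the risen was Ccr2 (6.19-fold, limma adjusted p = 0.0173), which effector T cells also express. Plasma cell markers (1 of 5 higher, 5 adjusted over the list alone, 1 after trimmed-mean scaling) and neutrophil markers (0 of 6, 0 adjusted over the list alone, 0 higher and 1 lower after trimmed-mean scaling) did not pass (camera adjusted p = 0.116 and 0.122, limma), although without KO 1 the plasma cell list did (0.00646); the neutrophil list was lower by camera with a median of 0.01 and a mean of 0.01 above the median gene. Cd8a was at 0.249 to 0.764 FPKM in the 4 libraries, and Cd8b1 at 10.3 to 11.3 FPKM. NK cell, platelet and stromal lists each had 2 tested members and the CD8 list 1, too few for a test. The X- and Y-linked genes did not pass (camera adjusted p = 0.935, limma), with a median and mean of -0.05 relative to the median gene and an upward camera direction, and Ddx3y was at 11.4 to 20.9 FPKM in all 4 libraries.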

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

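The settings without small RNA genes, without zeros and with the length trend removed were added after seeing the data; all others were planned. As deposited 2832 genes were higher and 111 lower in the libraries labelled KO, and the counts stayed within 1.5 times of these with both other pseudocounts, the stricter filter, limma without a trend, and the removal of small RNA genes or of zeros. The higher count was 1122 at a minimum of 2-fold, 179 after quantile normalization and 518 after trimmed-mean scaling; the lower count was 54 at 2-fold, 267 at a threshold of 0.1, 576 after trimmed-mean scaling, 171 with robust moderation and 50 with the length trend removed. With no filter limma called 3 higher and 0 lower of 20086 rows (4604 and 541 at an unadjusted p under 0.05). Leaving out 1 library gave 9 (without WT 1) to 2189 (without WT 2) higher and 0 (without WT 1) to 123 (without KO 2) lower; 5 of the 9 were among the 2832, and the lone library was assumed to vary like the other group. The replicate numbers do not pair the libraries in the labels, and the 2 differences between same-numbered libraries had a correlation of 0.108 across genes; with the number as a block 3909 genes were higher and 230 lower. Ripk1 kept its direction (log2) but was not past the threshold with no filter (0.73, adjusted p = 0.0884, limma), after quantile normalization (0.28), trimmed-mean scaling (0.31) or removal of the length trend (0.54); leaving out 1 library gave 0.67 to 0.79, and adjusted p over all its settings ran from 0.0073 to 0.257. The 13 lists higher became 0 with an estimated correlation and 1 with fry, and 11 to 18 under the other settings. The 4 lists lower became 0 with an estimated correlation and 0 with fry, 2 with no filter and 2 with the length trend removed, and 2 (without WT 2 or KO 1) to 5 (without WT 1) on leaving out 1 library. Of 131 called named genes, each counted once and Ripk1 left out, 89 passed after trimmed-mean scaling and 61 after quantile normalization. Most of these calls were lost when WT 1 was left out.

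Median changes of lists relative to the median gene that changed sign were those of histone genes (0.039 with no filter, 0.71 with the stricter filter, which left 12 members, and 0.10 with the length trend removed), of heat shock genes (0.093 with no filter and 0.018 after quantile normalization), of B cell markers (-0.012 with a pseudocount of 5), of neutrophil markers (-0.015 with a pseudocount of 5 and -0.19 with the stricter filter) and of X- and Y-linked genes (0.0077 with a pseudocount of 5, 0.13 with no filter and 0.023 with the stricter filter). On leaving out 1 library they ran from -0.018 to 0.52 for interferon gamma genes, from -0.077 to 0.83 for immediate early genes, from -0.57 to 0.19 for B cell markers, from -0.68 to 1.72 for neutrophil markers and from -0.098 to 0.014 for X- and Y-linked genes. Except for histone genes none of these lists had been called; without KO 1 the immediate early genes passed camera (limma, adjusted p = 5.96e-09), without KO 2 the interferon gamma genes did (adjusted p = 0.000566), and without WT 1 the neutrophil markers were lower (adjusted p = 0.0219). Genes that were not called changed sign after trimmed-mean scaling (Casp8 to -0.10, Cd79a to -0.16, Cd8b1 to -0.42, Ctss to -0.34 and Ddx3y to -0.026), after quantile normalization (Cd79a -0.26, Cd8b1 -0.41, Ctss -0.13) and with the length trend removed (Tyrobp 0.42, Pf4 0.39). On leaving out 1 library Cd79a ran from -0.084 to 0.51, Cd8b1 from -0.039 to 0.078, Tyrobp from -0.36 to 0.15, Ctss from -0.13 to 0.41, Siglech from -0.30 to 0.011, S100a9 from -0.52 to 2.21 and Pf4 from -0.33 to 0.047. The cause of these shifts was not tested, apart from the fewer rows or libraries that a filter or omission leaves. At about 17100000 to 21400000 fragments per library, a transcript of 2 kb at 1 FPKM rested on 30.7 to 38.5 fragments, and lower values on fewer. Mlkl and Cd8a were not tested because they did not pass the filter on low genes.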

Other observations

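The gene families and the explanations weighed in this part were chosen after the values were seen; the limma test of each gene and trimmed-mean scaling were planned. Every Fisher's exact test in this paragraph used the calls as deposited. Genes of MHC class II presentation were higher in the libraries labelled KO. As deposited 7 of 8 rose, against 25.6% of all tested genes (Fisher's exact test across genes, which are not independent, p = 0.000442, Benjamini-Hochberg adjusted over 7 families p = 0.00309). After trimmed-mean scaling 2 of the 8 class II genes rose, against 518 of all 11074 tested genes. H2-Ab1 rose from 2.27 ± 0.182 to 9.13 ± 3.04 FPKM (SD, n = 2 and 2; limma adjusted p = 0.0131), while Ciita, their transcriptional activator, was at 1.24 ± 0.290 and 1.15 ± 0.171 FPKM (limma adjusted p = 0.858). Of the 7, Cd74, H2-Aa, H2-Ab1 and H2-Eb1 are also the 4 risen members of the dendritic cell list, and of B cell genes Cd79b rose from 0.842 and 0.861 to 3.76 and 3.03 FPKM (limma adjusted p = 0.0134) and Cd22 2.64-fold (limma adjusted p = 0.0144), while Cd79a, Fcer2a, Xcr1 and Siglech were not called higher; where the rise came from was not tested. Of 14 chemokine receptor genes 6 rose as deposited, a share not shown to differ from that of all genes (adjusted p = 0.301, Fisher's exact test). After trimmed-mean scaling 6 rose and 2 fell. Cxcr5, the receptor that leads T cells to B cell follicles, rose from 3.59 ± 1.75 to 18.1 ± 2.19 FPKM (limma adjusted p = 0.0127). Ccr7, which leads to T cell zones, was at 72.6 ± 21.4 and 54.4 ± 16.1 FPKM (limma adjusted p = 0.334). Of 12 integrin genes 8 rose, 7 after trimmed-mean scaling (adjusted p = 0.0113, Fisher's exact test; 0.111 with 3 genes of integrin-binding proteins, which were first counted with them and taken out after the values were seen), among them Itgal, the LFA-1 subunit that binds ICAM-1, from 28.3 ± 2.83 to 96.3 ± 8.57 FPKM (limma adjusted p = 0.0115). Of 7 annexin genes 4 rose (1 after trimmed-mean scaling), of 8 S100 genes 4 (3), of 26 TNF and TNF receptor superfamily genes 9 (6, with 2 falling) and of 10 KLF genes 1 (0), none of the 4 past Fisher's exact test (adjusted p = 0.177, 0.214, 0.427 and 0.469).

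The myeloid marker genes given here, picked after the values were seen, ranged widely in value. Cxcr2, a neutrophil chemokine receptor, was at 75.3, 65.5, 54.7 and 50.6 FPKM in WT 1, WT 2, KO 1 and KO 2, Ms4a6c at 210, 171, 139 and 140 FPKM and Ctss at 65.4 to 98.4 FPKM, while S100a9, abundant in neutrophils, was at 2.12, 19.8, 8.34 and 21.3 FPKM and Lyz2, abundant in myeloid cells, at 0.164, 1.53, 2.99 and 4.38 FPKM. Of the CD8 genes, Cd8b1 was at 10.9, 10.5, 10.3 and 11.3 FPKM beside Cd8a at 0.434, 0.249, 0.764 and 0.251 FPKM. WT 2 lay between WT 1 and the libraries labelled KO for Tox2, of the follicular helper list, and Irf4, of the immediate early list. Tox2 was at 0.221, 1.93, 11.6 and 15.5 FPKM in WT 1, WT 2, KO 1 and KO 2, and Irf4 at 1.04, 5.39, 6.94 and 16.4 FPKM. Both were picked after the values were seen, and how many other genes do so was not counted.

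The fall of ribosomal protein genes is the pattern with the most members. In this paragraph and the next, the 95% intervals come from resampling genes, not libraries. They leave out the spread between libraries, and genes of a set are not independent, so the intervals are too narrow as a measure of uncertainty. Set against the 50 other tested genes nearest in transcript length they were still lower by a median of -0.905 (95% interval -1.0 to -0.837), although longer genes rose more (Spearman rho 0.302 across 10359 genes), so length bias may add to the fall but is not its whole source; scaling to the library total moves all genes of a library by 1 factor, and after trimmed-mean scaling the median was -1.36 (-1.42 to -1.30). Quantile normalization left -0.16 relative to the median gene. It gives every library the same set of values, so genes at the top ranks of every library can differ little after it. Rps21 and Rps24, both above 1000 FPKM in all 4 libraries, changed by -1.35 and -1.30 (log2) as deposited and by -0.50 and -0.41 after it. The small value is therefore no evidence against the fall, and how much of the shrinkage comes from this was not tested. For 20 genes of translation factors and related proteins the median difference was -0.572 (-0.733 to -0.190). Lengths were those of the longest annotated transcript, which may not be the one expressed. Where it is too long, a gene is set against genes that rose more, and the difference is overstated. The 1296 shortest other genes had a median change of 0.0654 (log2) as deposited, against -0.88 for the ribosomal protein genes. A wider fall across the translation machinery, as a candidate explanation, stays open. The genotype and a difference between preparations that follows the groups cannot be told apart, and no test here bears on either.

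The rise of follicular helper, regulatory and cell cycle genes was weighed against length bias and other cells in the preparation. With the length trend removed, the median of the 69 members was 1.07 above all genes (95% interval 0.933 to 1.24, against 1.03 before), with 58 past the threshold before and 58 after, which argues against length bias. The 6 B cell genes Cd79a, Cd79b, Ms4a1, Cd22, Blk and Pax5 rose together by 3.69 FPKM after trimmed-mean scaling. That is 0.84% of the summed rise of the members (439 FPKM). Cd79a was at most 4.90 FPKM, while Cd79b and Cd22 were called higher. The rise of these B cell genes was small, but what B cells would add to either sum is not known here. The cut-offs for this share were set after the values were seen, so it does not exclude B cells as a source. Erythroid cells may still have brought cell cycle transcripts. WT 2 showed a share of 0.361 of the rise of 3 globin genes. For the 23 cell cycle genes called higher, its share was -0.00389 (95% interval -0.0583 to 0.0532). A call favours genes with WT 1 and WT 2 close together, which by itself makes this share small, and the share rests on 1 library. It therefore does not decide the question. KO 1 exceeded KO 2 both in globin (log2 0.27) and in cell cycle genes (0.57). A larger share of activated, regulatory and follicular cells in the libraries labelled KO and a change within each cell both stay open as hypotheses, untested in bulk RNA.

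Ripk1 was higher, not lower, in the libraries labelled KO. Scaling is unlikely to hide a loss, because the log2 change was 0.308 after trimmed-mean scaling, with a 95% interval of -0.0818 to 0.698 that excludes a fall by 0.5. A deletion of some exons that leaves RNA of the others cannot be told apart from no deletion, since each library gives 1 value for Ripk1. Genotype labels exchanged between the groups also stay open, because 0 other labels differ between them.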
